A study of Drosophila melanogaster with 3 samples.

How the data were processed

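The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from whole Drosophila melanogaster embryos, aged 0 to 24 hours and of both sexes. The embryos came from a transgenic line that makes CG8089 with a green fluorescent protein (GFP) tag at its C-terminal end, and the precipitation used an antibody against GFP, per the labels. There was 1 group with 3 biological replicates, numbered 2, 3 and 4 in the labels, and therefore no contrast between conditions. The chromatin was sonicated to 200 to 800 bp, per the labels.

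Peaks were called by the authors for each replicate and for the pooled replicates, per the deposited file descriptions. Each call lists the alignments and 1 further file, which was taken to be the control because the authors' control-normalized tracks list it too. The control libraries were not analysed here. The peak caller, its version and the threshold of the irreproducible discovery rate (IDR) are not given in the sources used here. Each replicate list and the pooled list held 30000 entries, and the authors' reproducible list was the pooled list after their IDR step. The deposited lists give a signal value per peak, the authors' measure of peak strength, whose scale is not given in the sources used here. It was used to rank peaks within a list. The deposited lists also give −log10 of a q-value per peak. In the reproducible list 3193 of 3233 peaks had the highest −log10 q-value, 3.81, so it did not rank them. Read numbers per library were not given in the sources used here, so the depth is unknown and no precision was derived from it.

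The reproducible list was compared with the pooled list and was found to be its 3233 entries of highest signal. Reproducible against unreproduced peaks is therefore a contrast of strong with weak peaks, and the replicates are part of the pooled list. The 26232 unreproduced peaks that overlapped no reproducible peak were the background; 535 others overlapped one and were left out. The lists are on builds dm6 and dm3. Positions were annotated on dm6 only, with Ensembl release 115 (FlyBase annotation 6.54) and the Release 6 genome sequence, and all pooled peaks ended within its chromosomes. No coordinate was converted between builds. Transposable elements were left out of the gene set, which had 18164 genes on X, 2L, 2R, 3L, 3R and 4, of which 13945 were protein-coding.

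A promoter peak had its summit within 500 bp of an annotated transcription start site (TSS). Other summits were classed in the order 5' UTR, coding sequence, 3' UTR, noncoding exon, intron, intergenic. A replicate recovered a reproducible peak when the summit of 1 of its own 3233 strongest peaks lay inside it, and chance was measured with 1000 random draws from the replicate's list. Shares were compared with two-sided Fisher's exact tests, Woolf 95% intervals and Benjamini-Hochberg adjustment within each family: 7 annotation classes, 6 chromosomes, 31 gene lists, 18 motifs and 2080 6-mers. These tests count peaks or genes as independent and do not measure the spread between embryo collections; that spread is given as the SD over the strongest 3233 peaks of each of the 3 replicates. Motifs and 6-mers were searched on both strands within 100 bp of the summit, in 3233 reproducible and 3233 unreproduced peaks matched on promoter class and on GC content in bins of 5 percentage points.

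The comparisons, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. The rule took the gene with the nearest TSS for the 25 strongest peaks and for the 5 peaks whose rank differed most between replicates, up to 4 bound members of highest signal per gene list, CG8089, and the 10 6-mers with the lowest p. Genes named outside it are said to be so. The names h, calypso and Z4 of the fixed lists had no match in the annotation. A few single results are not reported here.

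The scripts were tested on simulated data. In a first simulation, 200 6-mers planted together in 5% of 3000 background sequences overwrote each other, and 171 of them were recovered while 481 others were called. Planted 10 per round with at most 1 insertion per sequence, 193 of 200 were recovered at a planted share of 5%, among them 39 of the 46 already present in at least 10% of background sequences, and 200 of 200 at 10%. Planting also called other words, 3.5 per round at 5% and 43.7 at 10%, so a called 6-mer can be a neighbour of the word that differs. With nothing planted, 0 of 2080 6-mers were called. All 20 simulated gene lists of 40 members with 50% bound were recovered, and 0 of 20 random lists of that size were called. Shorter lists, like many of the fixed ones, were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

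Alternatives were the stronger 1616 peaks, promoter windows of 250 and 1000 bp, other overlap rules, other backgrounds, the dm3 lists, and lists without each replicate. The last were the reproducible peaks holding a top summit of both remaining replicates. They are subsets of the reproducible list, so the replicate left out still had a part in the pooled peaks they come from. Leave-one-out versions of the peak count, the correlation and the chromosome shares were added after seeing the data.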

Results

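CG8089 binding was mapped by ChIP-seq in whole fly embryos of 0 to 24 hours that expressed CG8089 fused to GFP, with 3 biological replicates of 1 group. The question was where in the genome the tagged protein lies. The lists gave 3233 reproducible peaks on dm6 and 3063 on dm3. On dm6 the peaks had a median width of 396 bp, from 99 to 622 bp, and the authors' signal ran from 115.4 to 4668 with a median of 175. Of these dm6 peaks, 2054 held a top summit of both other replicates when replicate 2 was left out, 2119 without replicate 3 and 1892 without replicate 4. Read depth is unknown.

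At the tagged gene itself, a reproducible peak covered the start of CG8089 (FBgn0033993, minus strand, chromosome 2R, 15145825 to 15147824). The peak lay at 15147579 to 15147974, with its summit at 15147777, 47 bp inside the gene from the TSS. It ranked 1016 in the pooled list, with a signal of 229. Each replicate had its own peak there, at rank 2430 in replicate 2, 617 in replicate 3 and 1225 in replicate 4. No other reproducible summit lay within 5000 bp of the gene. The embryos carried a CG8089-GFP transgene and the control libraries were not analysed here. Signal from a transgene copy therefore cannot be told apart from binding at the gene itself.

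**Figure D1:**
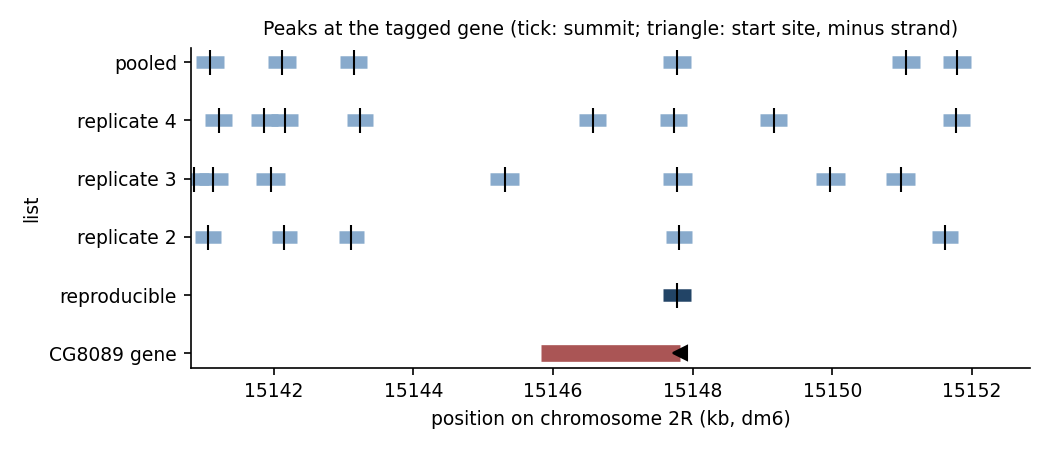
Peaks (bars) and summits (ticks) of each list around CG8089 on chromosome 2R, dm6, in kb. The reproducible peak with its summit at 15147777 lies over the start site, and all 3 replicates have a peak there.

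The strongest sites were shared by the replicates. The first-ranked peak was intronic, with the nearest TSS that of stw at 546 bp (chromosome 2R, 5416387 to 5417008, signal 4668), and it ranked 1 in each replicate. The next were a peak at the promoter of CG18081 (3L, 15835027 to 15835559, signal 2972, 56 bp from the TSS) and an intronic peak nearest to cbt, which encodes a zinc-finger transcription factor (2L, 480891 to 481291, signal 2313). Of the 25 strongest peaks, 16 were at promoters, 5 in introns and 4 intergenic, and all 25 were among the 3233 strongest peaks of every replicate.

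Promoter peaks among these 25 lay nearest to CG14100, px, Ugalt (a UDP-galactose transporter), ph-p (a Polycomb group gene), lncRNA:CR31840, Chro (a chromatin protein of interbands), CG1888, Maf1 (a repressor of RNA polymerase III), PNPase, Art3, CenG1A, mRpL41, Tcs5, lncRNA:CR44619 and CG31145. The peaks nearest to CG11050, Lk6 and cno were intronic. Those nearest to CG17544, the pseudogene CR43170, CG13323 and lncRNA:CR45643 were intergenic, with the CG13323 start site 11922 bp away.

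The replicates were then compared over the whole list. Replicate 2 recovered 78.0% of the reproducible peaks among its own strongest 3233, replicate 3 75.9% and replicate 4 80.5%, a mean of 78.1% ± 2.26 (SD, n = 3). Random peaks of the same lists gave 10.7%, 11.6% and 11.3%. The pooled list was made from these same replicates, so recovery above the random level follows in part from the design. Recovery fell with peak strength. Over 4 equal parts of the list it was 98.1% ± 0.99, 92.5% ± 3.86, 72.8% ± 3.22 and 49.2% ± 3.90 (SD, n = 3), from strongest to weakest. In all, 1679 peaks (51.9%) were recovered by 3 replicates, 1028 by 2, 484 by 1 and 42 by none.

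**Figure D2:**
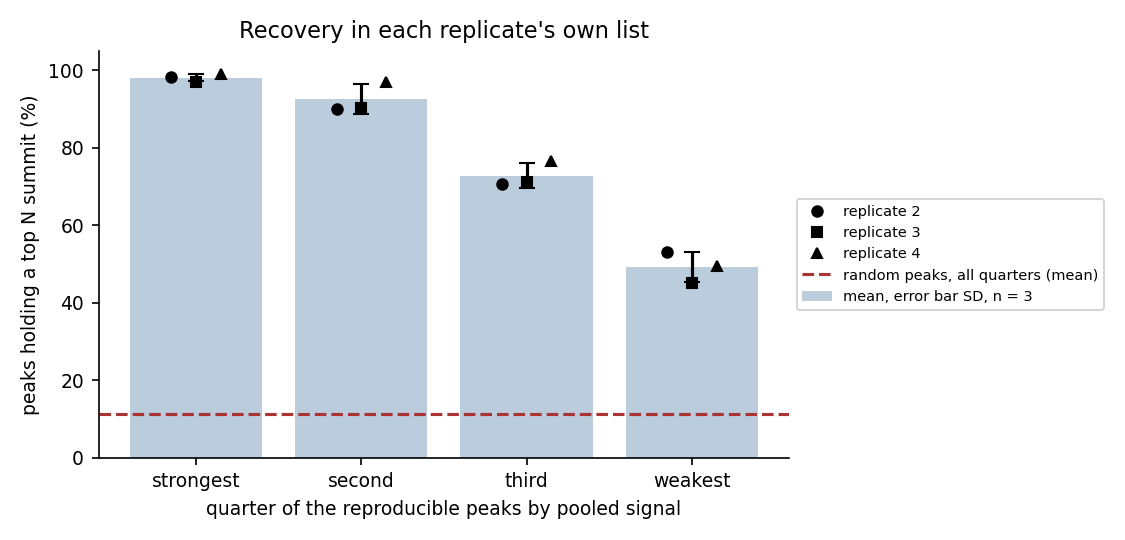
Share of reproducible peaks (percent) recovered in each replicate, by part of the list from strongest to weakest pooled signal; bars are means with SD, n = 3, points are replicates, and the dashed line is the mean for random peaks. Recovery goes from 98.1% in the strongest part to 49.2% in the weakest.

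Across reproducible peaks, which are not independent replicates, Spearman's correlation of signal was 0.483 between replicates 2 and 3 (2990 peaks), 0.664 between 2 and 4 (3029 peaks) and 0.635 between 3 and 4 (3131 peaks). Pearson's correlation of log2 signal was 0.58, 0.745 and 0.724. Among the 2966 reproducible peaks found in the lists of all 3 replicates, the ranks differed most at the peaks nearest to CG8132, lncRNA:CR44034, MESR4, FoxK and CG41128. Peaks missing from a replicate's list were not ranked here, although the replicates can differ more at those. The CG8132 peak ranked 119 in replicate 2 and 22322 in replicate 4, and the MESR4 peak ranked 286 in replicate 4 and 13922 in replicate 3. The CG8132 peak lies at a promoter shared with RpL34b, which is named here after its values were seen. It overlaps the stronger RpL34b peak (rank 191), and the replicate 2 summit of rank 119 lay in both.

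Peaks concentrated at promoters and were nearly missing from coding sequence outside promoters. Of 3233 reproducible summits, 1701 (52.6%) were within 500 bp of a TSS, against 7100 of 26232 (27.1%) unreproduced summits (odds ratio 2.99, 95% interval 2.78 to 3.22, Fisher's exact p = 2.1e-181). The promoter share in the strongest 3233 peaks of each replicate was 51.9% ± 0.68 (SD, n = 3). Coding sequence held 15 reproducible summits (0.464%) against 5515 (21.0%) unreproduced (odds ratio 0.0175, adjusted exact p = 6.1e-279), and 13.5% of random positions. In the replicates' strongest peaks the coding share was 1.58% ± 1.25 (SD, n = 3).

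The 5' UTR class fell from 1.30% of unreproduced to 0.650% of reproducible summits (adjusted exact p = 0.0013), 3' UTR from 1.67% to 0.804% (adjusted exact p = 1.2e-04) and intergenic from 16.0% to 12.9% (adjusted exact p = 7.2e-06). Intron shares were 31.7% and 32.0% (adjusted exact p = 0.78), and noncoding exons 0.804% and 0.903% (adjusted exact p = 0.725). Promoter summits were classed first and each share is of all summits, so a higher promoter share leaves less for these classes. Shares among summits outside promoters were not compared. The lower 5' UTR, 3' UTR and intergenic shares therefore need not mean avoidance, nor the like intron shares no change. Below the strongest 3233 peaks the replicates differed in promoter share, 17.8% in replicate 2, 33.05% in replicate 3 and 25.3% in replicate 4.

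**Figure D3:**
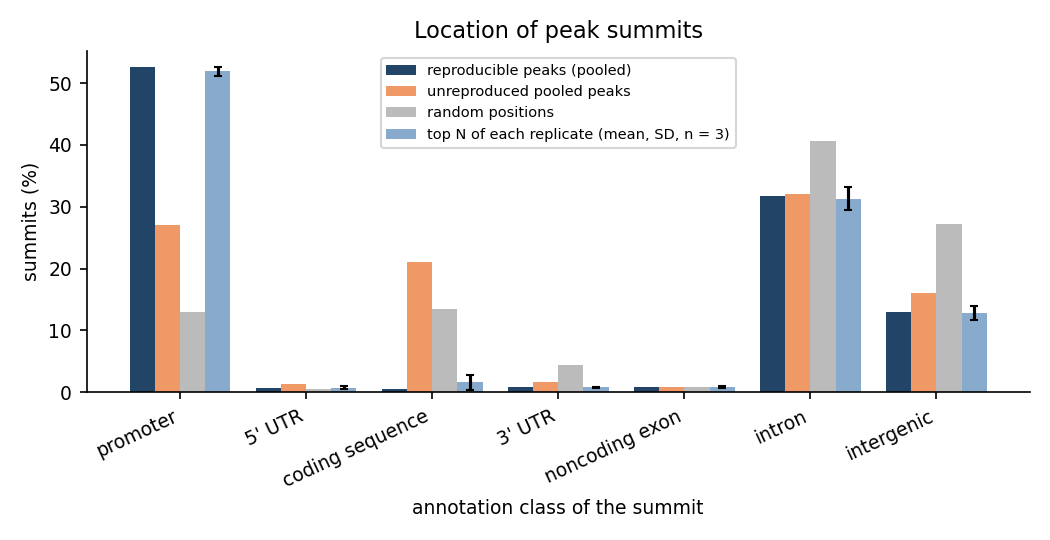
Share of summits (percent) in each annotation class for reproducible peaks, unreproduced pooled peaks, random positions and the strongest peaks of each replicate (mean, SD, n = 3). Promoters hold 52.6% of reproducible and 27.1% of unreproduced summits, and coding sequence 0.464% and 21.0%.

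By chromosome, X held 579 reproducible summits (17.9%) against 15.8% of unreproduced ones (odds ratio 1.16, 95% interval 1.05 to 1.28, adjusted exact p = 0.0075), and chromosome 4 held 43 (1.33%) against 0.778% (odds ratio 1.72, 1.24 to 2.39, adjusted exact p = 0.0075). Chromosomes 2L, 2R, 3L and 3R did not pass the test. Neither call held against chromosome length (X odds ratio 1.02, adjusted exact p = 0.753; chromosome 4 odds ratio 1.33, adjusted exact p = 0.154) or without replicate 2 (adjusted exact p = 0.124 for both), and chromosome 4 was also not called without replicate 3 or replicate 4 (adjusted exact p = 0.0639 and 0.281). Both calls were lost in the stronger 1616 peaks (adjusted exact p = 0.193 and 0.0916). Without replicate 3 the 2 chromosomes called were X (adjusted exact p = 0.0345) and an arm other than chromosome 4.

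Genes of the cytoplasmic ribosome stood out among the bound promoters. A reproducible summit lay within 500 bp of a TSS of 2247 genes, 12.4% of all genes, and of 2034 protein-coding genes (14.6%). For the cytoplasmic ribosomal protein genes it was 66 of 85 (77.6%), at 66 distinct peaks (odds ratio 25.3, 95% interval 15.2 to 42.3, adjusted exact p = 6.4e-42). Single replicates gave 74.5% ± 2.45 (SD, n = 3). The strongest were RpS27 (signal 977, summit 9 bp from the TSS), RpL7 (signal 837, 27 bp), RpL23A (signal 605, 107 bp) and RpL14 (signal 586, 3 bp).

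Genes for insulator and architectural proteins, which bind boundaries between chromatin domains, were bound in 9 of 14 cases (64.3%, odds ratio 12.8, adjusted exact p = 3.3e-05). The strongest were Chro, Trl, Cp190 and BEAF-32, with signals of 1619, 352, 311 and 165. Single replicates gave 45.2% ± 8.25 (SD, n = 3), and the call was lost without replicate 2 (28.6%, adjusted exact p = 0.0643; 35.7% without replicate 3 and without replicate 4) and in the stronger 1616 peaks (21.4%, adjusted exact p = 0.172). Polycomb and trithorax group genes, which maintain gene silencing and activity, were bound in 9 of 26 cases (34.6%, adjusted exact p = 0.00998), led by ph-p, Trl, Su(z)12 and pho; Trl is counted in both lists. That call was lost without replicate 2 or replicate 4 (11.5% each, adjusted exact p = 0.694 and 0.649), while single replicates gave 34.6% ± 3.85 (SD, n = 3). The ph-p and pho summits lay 493 and 409 bp from the TSS, near the limit of the window. With a 250 bp window the Polycomb and trithorax share was 26.9% (adjusted exact p = 0.0325).

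Cell cycle genes were bound in 10 of 36 cases (27.8%, adjusted exact p = 0.031), led by Dp, dup, dpa and Rbf2, and spliceosomal snRNA genes in 9 of 32 at 8 distinct peaks (28.1%, adjusted exact p = 0.037), led by snRNA:U6:96Ab, snRNA:U6:96Ac, snRNA:U1:95Ca and snRNA:7SKa, of which the 7SK RNA is not part of the spliceosome. The cell cycle call was lost without any 1 of the 3 replicates (16.7% to 19.4%, adjusted exact p = 0.0643 to 0.137), and the snRNA call without replicate 2 or replicate 4 (18.8% and 15.6%, adjusted exact p = 0.0928 and 0.187) or with windows of 250 or 1000 bp (adjusted exact p = 0.0711 and 0.128). In single replicates the shares were 28.7% ± 1.60 for cell cycle and 21.9% ± 3.1 for snRNA genes (SD, n = 3). The leave-one-out lists held fewer peaks, 1892 to 2119 against 3233, and the share of all genes in them is not given here. Lower shares in those lists need not mean that the replicates disagree. The Polycomb, cell cycle and snRNA calls were also lost among genes with any pooled peak at the promoter (adjusted exact p = 0.672, 0.811 and 0.118) and in the stronger 1616 peaks (adjusted exact p = 0.104, 0.553 and 0.816), and the cell cycle call with a 1000 bp window (adjusted exact p = 0.0609).

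Other groups were bound less often than the remaining genes. Chemoreceptor genes (0 of 185) and cuticle protein genes (0 of 122) had no bound promoter, which allows shares of up to 1.62% and 2.46%, with adjusted exact p = 7.0e-10 and 1.3e-06. tRNA genes were bound in 10 of 295 cases (3.39%, adjusted exact p = 9.4e-07), led by tRNA:Tyr-GTA-1-8, microRNA genes in 8 of 260 (3.08%, adjusted exact p = 1.3e-06), led by mir-9378, and snoRNA genes in 16 of 257 (6.23%, adjusted exact p = 0.006), led by snoRNA:U49:66Da, whose peak is that of RpL14. The peak of snoRNA:Or-CD11a is also that of a ribosomal protein gene, as are those of several weaker bound snoRNA genes. For microRNA and snoRNA genes the window was set at the annotated start of the gene. Whether transcription starts there was not tested, so low shares need not mean that their promoters are avoided. Without any 1 of the 3 replicates the microRNA share was 1.15%, and the tRNA share was 2.37%, 1.69% and 2.03% without replicates 2, 3 and 4, with both calls kept. The chemoreceptor call was lost among genes with any pooled peak at the promoter (adjusted exact p = 0.121). The snoRNA call was lost there (adjusted exact p = 0.51) and without replicate 2 or replicate 4 (adjusted exact p = 0.181 and 0.187) or in the stronger 1616 peaks (adjusted exact p = 0.172), and its direction turned with a 1000 bp window (17.1%, adjusted exact p = 0.592).

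Replication-dependent histone genes had 0 of 111 bound promoters (adjusted exact p = 3.6e-06). None of the 111 had any pooled peak either, weak or strong, and these genes are near-identical tandem copies, so their occupancy is uncertain.

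The remaining 20 lists did not pass the test. No Hox gene (0 of 8) and no pair-rule gene (0 of 8) was bound, with adjusted exact p = 0.784 for each, and lists of 8 genes allow shares of up to 37.5%. Mitochondrial ribosomal protein genes were at 15 of 73 (20.5%, adjusted exact p = 0.0977), with mRpS10, mRpS23, mRpL41 and mRpL23 strongest, and oxidative phosphorylation genes at 17 of 83 (20.5%, adjusted exact p = 0.0662), with ND-MWFE strongest. The mRpS10 and mRpS23 peaks are those named above for Art3 and CenG1A, whose start sites are nearer. Translation factor genes were at 12 of 51 (23.5%, adjusted exact p = 0.0662), with eIF6 and eEF1gamma strongest, and proteasome genes at 4 of 48 (8.33%, adjusted exact p = 0.723), with Rpn5 strongest.

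JNK, immediate-early and stress genes were at 5 of 15 (adjusted exact p = 0.0662), with Atf3 strongest, zinc-finger regulators at 8 of 32 (adjusted exact p = 0.1), with bowl, lola, CG8089 itself and pad strongest, circadian clock genes at 3 of 11 (sgg, dco and vri), ecdysone response genes at 4 of 17 (Eip75B, usp, Hr39 and ImpL2; adjusted exact p = 0.258 for both) and heat shock genes at 5 of 27 (adjusted exact p = 0.549), with Hsp83 strongest. Among developmental lists, segment polarity genes were at 3 of 13 (nkd, smo and pan; adjusted exact p = 0.345) and early zygotic genes at 2 of 10 (Sxl and Bro; adjusted exact p = 0.549). The gap and head (bcd), dorsoventral (rho and vnd), proneural (pros and brat), neuronal and glial (elav), Enhancer of split (E(spl)m7-HLH), muscle (sls and Mef2) and chorion lists had 1 or 2 bound members each, all at adjusted exact p of 0.884 or 1. The bound member of the chorion list was Cp190, which encodes an insulator protein and matched that list by its symbol only.

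**Figure D4:**
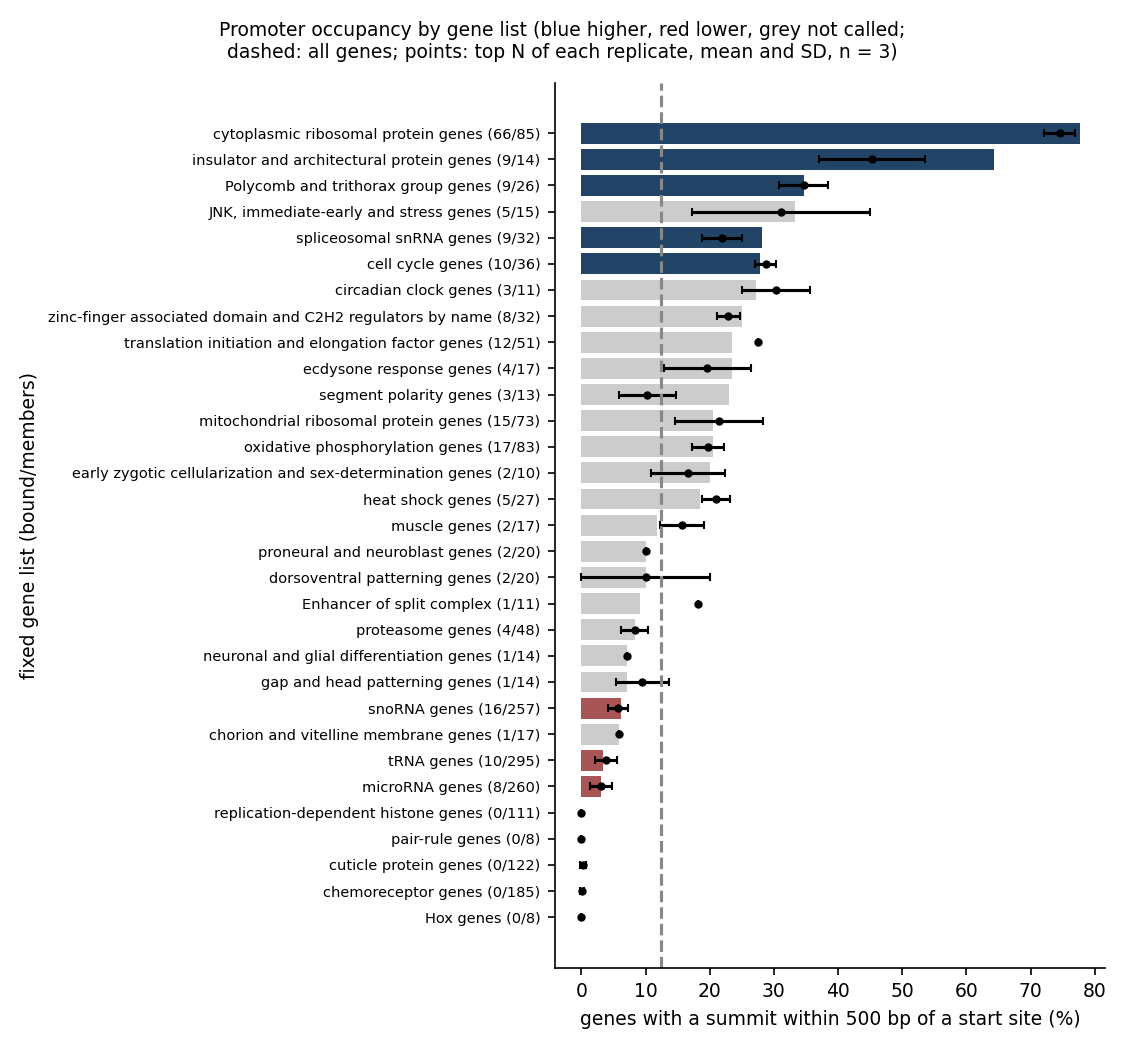
Share of genes (percent) with a reproducible summit within 500 bp of a TSS in each of the 31 gene lists, with bound and total members in the labels; points are single replicates' mean and SD, n = 3, and the dashed line is the share of all genes, 12.4%. Cytoplasmic ribosomal protein genes reach 77.6%.

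DNA elements under the peaks were compared with matched unreproduced peaks. The core site of CTCF, an insulator protein, occurred in 3.12% of 3233 reproducible peaks against 1.02% of 3233 matched peaks (odds ratio 3.13, 95% interval 2.10 to 4.65, adjusted exact p = 4.1e-08), and in 2.92% ± 0.686 (SD, n = 3) of the replicates' strongest peaks. The GAGA element, bound by the product of Trl, occurred in 4.73% against 3.22% (odds ratio 1.49, adjusted exact p = 0.0197). The GAGA call was lost without replicate 3 or replicate 4 (adjusted exact p = 0.848 and 0.179), within 50 bp of the summit and in the stronger 1616 peaks (adjusted exact p = 0.551 and 0.5), and against the peaks' own flanks the odds ratio was 0.957 (adjusted exact p = 0.775). None of the other 16 motifs passed, including DRE (3.80% against 2.88%, adjusted exact p = 0.146), the Zelda site (0.897% against 0.866%) and the Hox core (3.59% against 4.61%, adjusted exact p = 0.146).

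Of 2080 6-mers, 28 were more frequent and 30 less frequent under reproducible peaks. ACACTG had the lowest p, at 20.9% against 13.4% of peaks (ratio 1.56, adjusted exact p = 2.5e-12), with 18.8% ± 0.497 (SD, n = 3) in single replicates. ACAGTG (ratio 1.501), ACTGTG (1.55), CAGTGG (1.46), CTGTGC (1.45), CACTGA (1.39), AGTGTA (1.34) and CTCTCA (1.498) followed, with adjusted exact p from 2.1e-09 to 8.0e-04. GGAGGA and CAGGAC were less frequent (ratios 0.551 and 0.442, adjusted exact p = 0.00115 for both). In the stronger 1616 peaks ACTGTG, CACTGA, CTCTCA and CAGGAC were not called (adjusted exact p = 0.0929, 0.266, 0.0734 and 0.0734), nor were CTCTCA and CAGGAC without replicate 3 (adjusted exact p = 0.0687 and 0.228).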

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

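The tests against the other housekeeping lists and of the reproducible summits alone against their own flanks were chosen only after the result was seen. On dm3, 37 reproducible peaks lay on scaffolds outside the chromosome arms, 16 on 2RHet, 13 on 3LHet, 5 on 3RHet and 3 on 2LHet. They were noted because the comparisons were run on dm6, where 0 reproducible peaks lay off the arms. Coordinates were not converted between builds, so whether the same sites are among the dm6 peaks on the arms was not tested. They made up 1.21% of the reproducible list, against 0.587% of the whole pooled list and 0.273% to 2.09% of the whole replicate lists on dm3. The whole lists hold 30000 entries each, and the strongest 3063 peaks of each replicate were not compared.

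Ribosomal protein promoters were bound far more often than other genes. Occupancy that comes up alike at every housekeeping promoter is argued against by 66 of 85 ribosomal protein genes against 48 of 255 genes of the mitochondrial ribosome, proteasome, oxidative phosphorylation and translation factor lists (odds ratio 14.98, 95% interval 8.23 to 27.3). With genes stratified on promoter GC content and number of start sites, the odds ratio against other protein-coding genes was still 18.3 (10.5 to 31.6). Among bound promoters, at least 1 of the 6 enriched 6-mers with the lowest p lay under 42.4% of ribosomal protein peaks and 50.4% of other promoter peaks (odds ratio 0.725, 0.441 to 1.19). Bound ribosomal protein promoters were therefore not richer in these words than other bound promoters. Unbound promoters were not searched, so this cannot tell whether the words account for the higher occupancy. Transcription level and the control libraries were not analysed here, so signal that follows very high transcription stays open, and no biological explanation was tested.

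Reproducible summits were poor in GC, 38.3% against 47.2% for unreproduced ones. Absence from coding sequence is argued against as the whole cause for intron and intergenic summits, where reproducible ones were lower by more than 5 percentage points. The difference was -5.70 (95% interval -6.10 to -5.30) in introns and -5.71 (-6.33 to -5.08) for intergenic summits, whose interval came nearest to 0. Promoter summits differed by -7.42, but they can lie in coding sequence, so that class cannot test this. The wider region is argued against by GC at the summit minus GC of its own flanks, which differed by -9.34 percentage points, reproducible minus unreproduced (-9.72 to -8.97). Part of that lay in the unreproduced summits, at 5.15 relative to their flanks, but reproducible summits lay at -4.19 relative to theirs (-4.54 to -3.84). A GC bias shared by all libraries stays open; the mean over the replicates' strongest peaks was 39.1% ± 0.549 (SD, n = 3).

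CTCF core matches were enriched under reproducible peaks. Promoter location is argued against, since outside promoters the odds ratio was 4.34 (95% interval 2.46 to 7.65; 63 against 15 of 1532 peaks). Of 118 matches within 100 bp, 82 (69.5%, exact binomial interval 60.3 to 77.6, p = 2.8e-05) lay within 50 bp of the summit. This is consistent with the element marking the sites themselves, as a hypothesis found and tested on the same peaks. Chromatin accessibility and the control libraries were not analysed here, and whether CG8089 or another protein binds there was not tested.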

How the results depend on the processing

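The leave-one-out versions of the peak count, the correlation and the chromosome shares were chosen only after the result was seen. No paired analysis was possible because there was 1 group. The promoter call held in all alternatives (odds ratio 2.39 to 7.48), as did the calls for cytoplasmic ribosomal protein, cuticle, tRNA and microRNA genes and the CTCF core; histone genes had no pooled peak, so the background of genes with any pooled peak gave them no value. Of 198 alternatives, 28 of the summary values stayed and 20 moved, and among single lists, chromosomes, motifs and 6-mers 107 calls stayed, 41 were lost and 2 turned direction. The unknown depth limits what the weaker peaks can show. Stricter and leave-one-out lists hold fewer peaks, yet some gave more calls (13 gene lists without replicate 3, 60 6-mers without replicate 2), and the causes were not tested.

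The stronger 1616 peaks gave 0 chromosome, 7 gene list and 15 6-mer calls, against 2, 11 and 58. Without each replicate in turn, 1892 to 2119 peaks, correlations from 0.483 to 0.664 (mean of all pairs 0.594), 0 to 2 chromosome calls and 7 to 13 gene list calls were found. Mean recovery was 70.0% with 50% reciprocal overlap, 75.8% with summits within 100 bp and 91.2% among 2 times as many replicate peaks. Chromosome length as background gave 0 calls, and genes with any pooled peak 5 list calls. Motif calls were 1 within 50 bp, 11 against flanks and 12 against all unreproduced peaks without matching, and 6-mer calls 1232 against flanks, where GC content also differs. The direction turned for snoRNA genes within 1000 bp (17.1%) and for the GAGA element against flanks (0.957).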

Other observations

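The tests of the name stems and of the 9-mers were chosen only after the result was seen, and the genes named from these stems were chosen after their values were seen. Beyond the fixed lists, 95 groups of protein-coding genes that share a name stem, with at least 8 members each, were compared with all other protein-coding genes. Of these, 10 were called, among them the ribosomal protein and cuticle protein stems. PIG genes, which build the glycolipid anchor of surface proteins, were bound in 9 of 21 cases (42.9%, adjusted exact p = 0.0194), led by PIG-F (signal 630) and PIG-M (signal 400). Vha genes, which encode subunits of the vacuolar proton pump, were bound in 9 of 22 (40.9%, adjusted exact p = 0.0255), led by Vha100-2 (signal 448). Single replicates gave 38.1% ± 0 for PIG and 33.3% ± 9.46 for Vha genes (SD, n = 3).

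Cytochrome P450 (Cyp) genes were bound in 1 of 85 cases, Cyp6u1 (adjusted exact p = 7.2e-04), and odorant-binding protein (Obp) genes in 1 of 51, Obp99b (adjusted exact p = 0.0464). Of the histone genes by name, His2Av and His3.3B, which encode variant histones, were bound; the share for this stem is not given, as the replication-dependent copies had no pooled peak at all. The 10 bound genes of the pre stem are annotated pieces of mod(mdg4) at 1 shared peak. Summits on annotated transposable elements made up 0.433% of reproducible and 0.507% of unreproduced peaks (Fisher's exact p = 0.691).

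Genes with a divergent start site were bound more often. Protein-coding genes with a start site of another gene facing away within 500 bp were bound in 1104 of 4134 cases (26.7%) against 930 of 9811 (9.48%), an odds ratio of 3.48 (95% interval 3.16 to 3.83), and 2.80 to 3.89 in single replicates. Part of this comes from 1 peak counting for both genes. With each peak given only to the gene of its nearest start site, the odds ratio was 1.75 (1.56 to 1.95), so shared counting accounts for part and is argued against as the whole cause. Any start site of a gene could make it divergent or bound, and genes were not matched on their number of start sites. Whether the summits lay at the divergent start sites themselves was not tested.

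Longer words under the summits held across chromosomes against flanks, but mostly not against other peaks. The 10 9-mers most over their flanks on 2L, 2R and X were also over their flanks on 3L and 3R (10 of 10). GC content differs between summit and flank, and 4 of the words hold all or part of the DRE, which did not pass against matched peaks (adjusted exact p = 0.146). Against 1387 unreproduced peaks matched on promoter class and GC content, 1 of the 10 passed on 3L and 3R. This was CTGAGAGAA, in 25 of 1387 reproducible peaks (1.80%) and 7 matched peaks (odds ratio 3.62, 95% interval 1.56 to 8.39, adjusted exact p = 0.0198). CACTGAGAG, which overlaps it, was in 22 and 8 (adjusted exact p = 0.062) and CCACTGTGC in 20 and 7 (adjusted exact p = 0.062). A difference in base composition, or words that weak and strong peaks share, stays open for the others, and which protein binds these words was not tested.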
